A study of Arabidopsis thaliana with 2 samples.

How the data were processed

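The labels describe 2 libraries from MYB3R3-GFP seedlings: 1 ChIP library made with an anti-GFP antibody, and 1 input library. The ChIP library had a deposited peak list, which was used; the input library was not analysed here. Per the submitters' processing notes, the tools were Bowtie 0.12.7, SAMtools 0.1.18 and MACS2, with no version given for MACS2, and the genome build was TAIR10; the notes give no role for each tool. How the input was used, the threshold for calling a peak and the number of mapped reads are not given in the sources used here.

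The list gave a chromosome, a start, an end, a running name and a score for each of 2931 peaks. The score is a number per peak that the authors deposited, and its formula (a p-value or q-value, its log base and any factor) is not given in the sources used here. It was used only to rank and filter peaks within this list. The start and end are other deposited values, in base pairs on TAIR10, with the start taken to count from 0 as in BED files; coordinates are printed counting from 1. No summit was used, so the midpoint of a peak stood for its position.

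Gene names and positions came from a table of the TAIR10.1 assembly with 27444 protein-coding genes on the 5 nuclear chromosomes. Since its name differs from the build of the peaks, the match was checked by shifting the peaks by up to 5000 bp in steps of 100 bp. The share of peak midpoints within 500 bp of a gene end was 77.3% without a shift, against a median of 40.7% at shifts of 4000 bp or more, and on each chromosome the best shift was within 100 bp of 0. Coordinates of genes are not printed. The table's largest gene end stood for the length of each chromosome.

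Strand, exons and genome sequence were not used here, which changed the design fixed before the data were examined. Windows around transcription start sites became windows from 1000 bp outside to 200 bp inside both ends of a gene, and random lists were matched on the total intergenic space to both sides of a gene, in 20 bins, instead of the space upstream. Bound genes therefore include genes with a peak at the 3′ end. The planned motif comparisons needed sequence and were not run, and peaks are not assigned to exons, introns or untranslated regions.

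A gene was bound if a peak overlapped 1 of its windows by at least 1 bp, and its score was that of its highest peak. A peak that touched several genes counted for each. For 10 gene lists fixed before the data were examined (240 loci, all found in the table, 4 lists as controls), bound members were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 10 lists, and with 10000 matched random lists. Peaks of 1 library are not replicates, so these p-values describe the list and not the spread between plants. Shares have 95% Wilson intervals and a share of 0 has the upper limit that 3 counts give; both cover counting error only. Peak positions were compared with 1000 random placements of the same peaks on the same chromosome. Contrasts between lists and the contrasts of scores were chosen after the data were seen.

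Genes were named by a rule fixed before the data were examined: the gene nearest to each of the 10 highest peaks (by gene end, in place of the transcription start site), the highest-scoring bound members of each list (up to 8 for the G2/M, cytokinesis and replication lists, up to 4 for the others), MYB3R1 to MYB3R5, CYCB1;1, CYCB1;2, CDC20.1, KNOLLE and PCNA1. List members that were not bound, and families within lists, were named after their values were seen. The gene table calls MYB3R1 PC-MYB1 and LHCB1.3 CAB1, and gives RSW7, CAP-D2, SMR4, H4g and the HTR genes by locus code alone. For these the names of the fixed lists are printed. The kinesin gene AT2G36200, labelled KRP125C in the fixed list, also has no other symbol there. It goes by locus code here, since that label could not be verified.

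Alternatives were windows of 500 and 2000 bp outside each end, the higher-scoring 1467 and 733 peaks, a midpoint in place of any overlap, and the nearest gene end alone. Added after the data were seen were peaks anywhere in the gene, peaks that touched 1 gene, random placement within 50000 bp, and expected counts per chromosome from gene number. The list test was tested on 50 simulated sets of 2931 peaks over 27444 genes with 60% of the members of 2 lists planted. In these sets 100% of planted lists and 0.25% of tests of the 8 other lists passed the threshold of 0.05. Planted peaks were set directly at gene ends, so their detection was built in. The other simulated peaks were spread at random along each chromosome and did not gather at gene ends as the real peaks do. The simulation therefore checks the code and does not give the rate of false calls for the real list. Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.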

Results

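MYB3R3 is one of the 5 Arabidopsis MYB proteins with 3 MYB repeats, a family known for acting on genes of the mitotic cell cycle. The data came from whole Col-0 seedlings, 9 days after germination, that carried MYB3R3 fused to green fluorescent protein (GFP). Chromatin was precipitated with an antibody against GFP and sequenced as 1 ChIP library, beside 1 library of input DNA from plants of the same line. The ChIP library was analysed as its deposited list of 2931 peaks, and the input library was not analysed here. The number of reads behind the peaks is unknown from the list. With 1 ChIP library there was no replicate error, so each test below describes this list of peaks, and genes or peaks did not serve as replicates. The series asks which genes MYB3R3 binds.

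The peaks lay on all 5 nuclear chromosomes and had a median width of 275 bp, with quartiles of 225 and 362 bp and a range from 196 to 1495 bp. They covered 920.9 kb in total and none overlapped another. Each peak carried a score given by the authors, with a median of 17.4, quartiles of 12.0 and 28.5, and a range from 4.13 to 749.6. A score above 100 was reached by 137 peaks. Chromosome 2 held 412 peaks against 484.6 expected from its length, a ratio of 0.850 (permutation test by 10000 random placements, two-sided, adjusted p = 0.0030 over 5 chromosomes). The other chromosomes had ratios between 0.938 and 1.06, with adjusted p of 0.184 or more. When the expected count followed the number of protein-coding genes, the ratio for chromosome 2 was 0.894 and no longer passed the permutation test (adjusted p = 0.0655).

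Peaks gathered at the ends of protein-coding genes. The midpoints of 2282 of the 2931 peaks (77.9%) lay in a window from 1000 bp outside to 200 bp inside a gene end, against 42.3% ± 0.925 (SD over 1000 random placements on the same chromosome), a 1.84-fold difference (permutation p = 0.0020, two-sided, the smallest that 1000 placements allow). With random placement within 50000 bp of each peak, added after the data were seen, the random share was 49.4% and the difference 1.58-fold. The shares by position below were compared with placement along the whole chromosome only. Inside genes, 988 midpoints (33.7%) lay within 200 bp of an end, 3.54 times the random share of 9.52%. Another 910 (31.0%) lay outside genes within 500 bp of an end, 2.34 times the random share of 13.3%. Positions deeper inside genes held 630 midpoints (21.5%), which was 0.480 times the random share, and positions over 1000 bp from any gene held 230 (7.85%), or 0.310 times the random share. Among the 733 peaks with the highest scores, 14.6% lay deeper than 200 bp inside a gene, and among the 734 with the lowest scores 31.3% did; this difference was not tested. The direction of transcription was not used here, so a gene end could be the 5′ or the 3′ end.

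**Figure D1:**
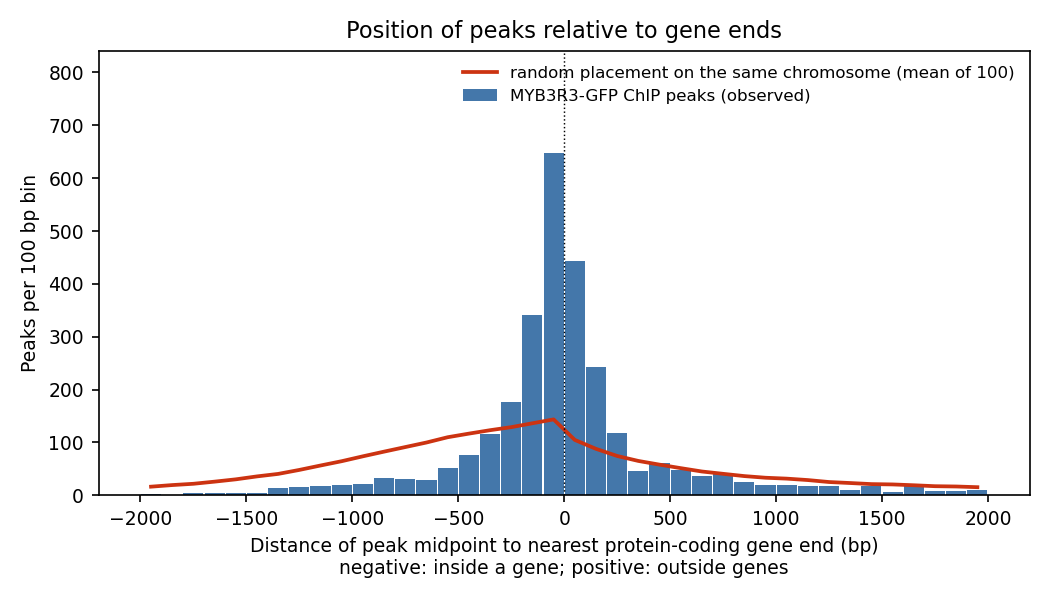
Distance in bp from each peak midpoint to the nearest end of a protein-coding gene (x axis, negative inside a gene) against the number of peaks per 100 bp bin (y axis). Bars show the observed peaks and the line the mean of 100 random placements on the same chromosome; the observed peaks pile up at the gene end, and 33.7% of all midpoints lay inside a gene within 200 bp of an end.

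A gene was called bound when a peak overlapped the window at either of its ends. This gave 3582 bound genes among 27444 protein-coding genes (13.1%), of which 3273 had 1 peak and 309 had 2 or more. Neighbouring genes often shared a peak: 1327 peaks (45.3%) touched the windows of 2 or more genes, 1143 touched 1 gene and 461 (15.7%) touched none. With only the peaks that touched 1 gene, 1102 genes were bound, and with the 733 highest-scoring peaks 1091 were.

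The highest score of the list, 749.6, belonged to a peak on chromosome 5 from 16201764 to 16202269 (TAIR10), with its midpoint outside genes and nearest to AT5G40460. The next 3 peaks had their midpoints inside a gene, and the nearest gene end of each was that of a gene of mitosis. RSW7 (AT2G28620), a kinesin-5 motor of the spindle, had a score of 652 (chromosome 2, 12270425 to 12271044). CYCA1;1, an A-type cyclin, had 568 (chromosome 1, 16777037 to 16777656). CAP-D2 (AT3G57060), a condensin subunit, had 479 (chromosome 3, 21120640 to 21121526), and its peak also touched AT3G57062. The peaks ranked 5 to 10 were nearest to AT5G54970, AT1G72250, AT3G12870, AT1G14260, AT4G38062 and AT5G45700, with scores from 434.8 down to 338.5. Of these 6 peaks, those at AT1G72250 and AT1G14260 touched 1 gene each, and the others touched 2 or 3.

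Genes of the G2/M phase and mitosis were bound in 32 of 39 cases (82.1%, 95% Wilson interval 67.3 to 91.0%), against 13.0% of all other protein-coding genes. The highest scores after CYCA1;1 and CAP-D2 were those of CKS2 (a subunit of cyclin-dependent kinases, 247.8), TPX2 (spindle assembly, 214.8), UVI4-LIKE (also called GIG1, an inhibitor of the anaphase-promoting complex, 187.7), CDKB1;1 (a mitotic cyclin-dependent kinase, 104.6), PPK1 (listed as MPS1, AT1G77720, 97.1) and CDC20.1 (an activator of the anaphase-promoting complex, 94.6). All 4 CDKB genes and 8 of the 9 B-type cyclin genes of the list were bound, among them CYCB1;2 (CYC1BAT in the gene table) with a score of 85.7 and CYCB1;1 with 16.8 (chromosome 4, 17624220 to 17624549), which was below the median of all peaks. The 7 members without a peak at a gene end were CYCA2;2, CYCA2;4, CYCB2;1, CCS52B, AUR2, AUR3 and PANS1. When peaks anywhere in the gene also counted, 34 of the 39 genes were bound. The odds ratio of the list was 30.7 (95% interval 13.3 to 82.5; Fisher's exact test, two-sided, adjusted p = 2.46e-21 over 10 lists). Random lists matched on the intergenic space around their genes held 5.20 bound genes on average and at most 14 in 10000 draws. With only the peaks that touched 1 gene, 12 of the 39 genes were bound and the odds ratio was 10.7.

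Genes of cytokinesis and mitotic kinesins were bound in 14 of 17 cases (82.4%, 59.0 to 93.8%). Below RSW7, the highest scores were those of KNOLLE (also called SYP111, the syntaxin of the cell plate, 159.2) and the kinesin gene AT2G36200 (143.9). Next came KINESIN-12B (also called PAKRP1L, a kinesin of the phragmoplast, 130.9), CSLD5 (a cellulose synthase-like protein, 104.6), ATK5 (a kinesin-14, 98.8), HIK (the HINKEL kinesin of cytokinesis, 95.7) and ATK1 (a kinesin-14, 92.1). The KNOLLE peak lay on chromosome 1 from 2710829 to 2711314 and touched 2 genes. TES, KEULE and SNAP33 had no peak. The odds ratio was 31.2 (8.70 to 169; Fisher's exact test, adjusted p = 6.26e-10), and 10.001 with only the peaks that touched 1 gene.

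Genes of DNA replication and S phase were bound in 29 of 33 cases (87.9%, 72.7 to 95.2%). The highest scores were those of CDC6 (listed as CDC6A, licensing of replication origins, 322.3; chromosome 2, 12689156 to 12689750, a peak shared with AT2G29679), FAS1 (a subunit of chromatin assembly factor 1, 195.3), WEE1 (a kinase of the replication checkpoint, 141.4), RNR1 (the large subunit of ribonucleotide reductase, 140.6), PCNA2 (the sliding clamp, 130.9), MCM6 (the replicative helicase, 124.9), ICU2 (the catalytic subunit of DNA polymerase alpha, 122.7) and ORC1B (the origin recognition complex, 108.4). All 6 MCM genes and 6 of 7 ORC genes were bound, and PCNA1 had a score of 54.7. ORC5, RNR2A, POL2A and MSI1 had no peak at a gene end. When peaks anywhere in the gene also counted, 30 of the 33 genes were bound. The odds ratio was 48.7 (17.1 to 191; Fisher's exact test, adjusted p = 2.46e-21), and 9.03 with only the peaks that touched 1 gene. The share of bound genes in the mitosis and cytokinesis lists together, 46 of 56, was not distinguishable from that of the replication list (Fisher's exact test, adjusted p = 0.651 over 7 contrasts chosen after the data were seen). Median scores were 77.5 for the bound mitosis and cytokinesis genes and 69.2 for the bound replication genes (permutation test, 100000 resamples, p = 0.551).

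Core histone genes were bound less often than replication genes, in 11 of 23 cases (47.8%, 29.2 to 67.0%; Fisher's exact test of the difference, adjusted p = 0.00731). HTR13 and HTR9, both encoding histone H3, shared a peak with a score of 89.8, and the histone H4 gene H4g (AT5G59690) and the H3 gene HTR2 had 86.1 and 52.5. Of the histone families, 4 of 5 H3.1 genes, 3 of 8 H4 genes, 2 of 6 H2B genes and 2 of 4 H2A genes were bound. The odds ratio of the list was 6.12 (2.45 to 15.2; Fisher's exact test, adjusted p = 9.14e-05). With only the peaks that touched 1 gene, 1 of the 23 genes was bound and the list no longer passed Fisher's exact test (odds ratio 1.09, adjusted p = 0.763).

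**Figure D2:**
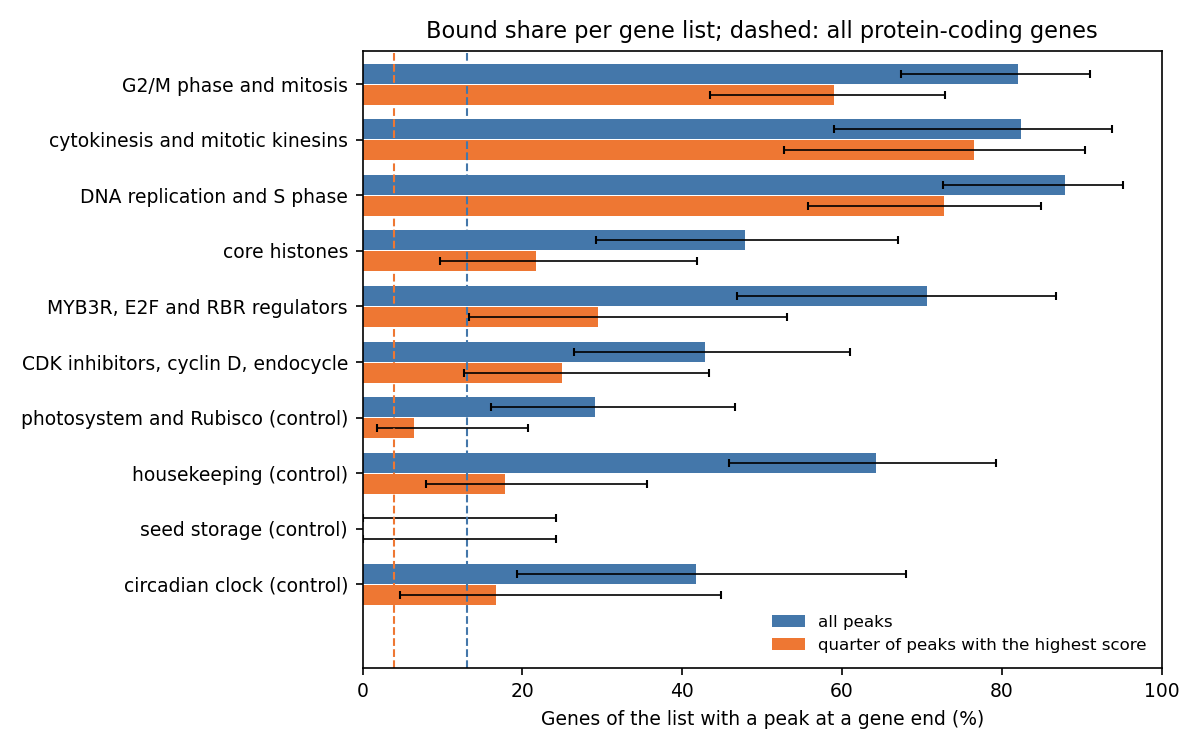
Share of genes with a peak at a gene end, in percent (x axis), for each of the 10 fixed gene lists (y axis), from all 2931 peaks and from the 733 with the highest scores; error bars are 95% Wilson intervals and dashed lines the shares of all protein-coding genes (13.1% and 3.98%). The G2/M, cytokinesis and replication lists lay between 82.1% and 87.9% with all peaks, and the seed storage list was at 0.

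Genes of the regulators MYB3R, E2F and RBR were bound in 12 of 17 cases (70.6%, 46.9 to 86.7%). RBR1, the Arabidopsis retinoblastoma protein, had the highest score, 263 (chromosome 3, 3918926 to 3919520). MYB3R3 itself followed with 124.9 (chromosome 3, 2878852 to 2879626), in a peak of 775 bp that touched 2 genes. Whether this signal came from the endogenous MYB3R3 gene or from the transgene was not determined here. The atypical E2F gene DEL3 had 70.3, MYB3R4 32.8, MYB3R1 25.02 and MYB3R5 20.7, while MYB3R2 had no peak. The odds ratio of the list was 16.04 (5.25 to 58.1; Fisher's exact test, adjusted p = 1.57e-07), and 5.13 with only the peaks that touched 1 gene.

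Genes of CDK inhibitors, D-type cyclins and endocycle entry were bound in 12 of 28 cases (42.9%, 26.5 to 60.9%). SMR4 (a SIAMESE-related CDK inhibitor, AT5G02220), CYCD4;1, UVI4 (an inhibitor of the anaphase-promoting complex) and CYCD1;1 had scores of 274.9, 273.5, 203 and 167.4. By family, 5 of 10 D-type cyclin genes, 3 of 7 SIM and SMR genes and 2 of 7 KRP genes were bound. The odds ratio was 5.01 (2.16 to 11.3; Fisher's exact test, adjusted p = 0.000137), and 13.4 with only the peaks that touched 1 gene.

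Among the 4 control lists, housekeeping genes were bound more often than photosystem and Rubisco genes (Fisher's exact test of the difference, adjusted p = 0.0216). Housekeeping genes were bound in 18 of 28 cases (64.3%, 45.8 to 79.3%; odds ratio 12.0, 5.27 to 29.2; Fisher's exact test, adjusted p = 1.03e-09), led by TUA2 (alpha-tubulin, 145.1), TUB7 (beta-tubulin, 119.2), ACT7 (actin, 100.9) and TUB3 (beta-tubulin, 93.9). Peaks that touched 1 gene left 8 of the 28 bound (odds ratio 9.62, Fisher's exact test, adjusted p = 2.5e-05). Photosystem and Rubisco genes were bound in 9 of 31 cases (29.0%, 16.1 to 46.6%; odds ratio 2.73, 1.11 to 6.17; Fisher's exact test, adjusted p = 0.0165), led by LHCB6 (33.6), LHCB1.3 (30.8), PSAF (22.8) and LHCB4.1 (17.4), and none of the 4 Rubisco small subunit genes was bound. With only the peaks that touched 1 gene, the photosystem and Rubisco odds ratio was 0.797 (Fisher's exact test, adjusted p = 1). Circadian clock genes were bound in 5 of 12 cases (41.7%, 19.3 to 68.0%; odds ratio 4.76, 1.19 to 17.4; Fisher's exact test, adjusted p = 0.0165), with scores of 48.8 for PRR7, 38.9 for PRR9, 10.5 for RVE8 and 10.2 for CCA1. This list did not pass Fisher's exact test with windows of 500 bp (odds ratio 2.70, adjusted p = 0.153). Seed storage and late embryogenesis genes were bound in 0 of 12 cases, which allows a share of up to 25%, and did not differ from other genes (Fisher's exact test, adjusted p = 0.386).

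Genes of the G2/M, cytokinesis and replication lists stood apart by score from housekeeping, photosystem and Rubisco genes. Not all cell cycle lists did so. Median scores were 25.5 for the bound core histone genes and 22.9 for the bound MYB3R, E2F and RBR genes. The median of all bound genes was 18.9, and the bound genes of CDK inhibitors, D-type cyclins and endocycle entry had 57.9. The 75 bound genes of the G2/M, cytokinesis and replication lists had a median score of 73.3, and the 27 bound housekeeping, photosystem and Rubisco genes had 17.4 (permutation test, 100000 resamples, two-sided, p = 0.00012, adjusted p = 0.00024 over 2 score contrasts). Across all peaks, 75 of 89 genes of the 3 cell cycle lists (84.3%) and 18 of 28 housekeeping genes (64.3%) were bound, a difference that did not pass the correction (Fisher's exact test, adjusted p = 0.0554). With the 733 highest-scoring peaks the counts were 60 of 89 (67.4%) and 5 of 28 (17.9%; Fisher's exact test, adjusted p = 4.11e-05).

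**Figure D3:**
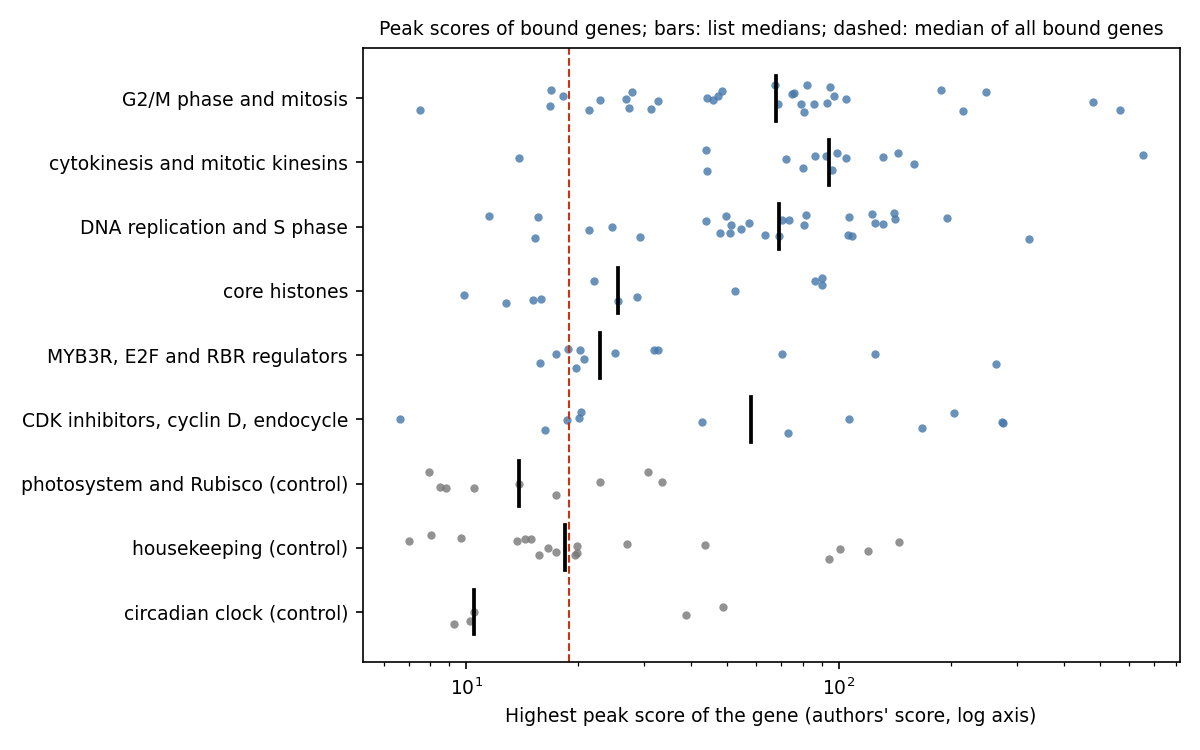
Highest peak score of each bound gene (x axis, log scale, the authors' score) by fixed gene list (y axis); each point is 1 gene, black bars are list medians and the dashed line is the median of all bound genes (18.9). Median scores were 67.9 for G2/M, 93.9 for cytokinesis and 69.2 for replication genes, against 18.5 for housekeeping and 13.9 for photosystem and Rubisco genes. Core histone genes had 25.5 and the MYB3R, E2F and RBR regulators 22.9.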

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

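Tests added after the data were seen were those with peaks anywhere in the gene, with peaks that touched 1 gene, with local random placement and with gene number per chromosome. Of 93 alternatives, 85 had a test (the list counts and the share at gene ends): 75 kept their direction and side of the threshold, 9 no longer passed and 1 turned its direction. The counts per chromosome against gene number are not among the 93. Of those, 4 kept their direction and side and 1 no longer passed. Of the 8 for the number of bound genes, which has no test, 5 stayed within 1.5 times and 3 did not. The odds ratio ranged from 10.7 to 42.3 for the G2/M list, 10.001 to 79.4 for cytokinesis, 9.03 to 65.8 for replication, 5.13 to 24.9 for the regulators, 4.26 to 13.4 for CDK inhibitors and D-type cyclins, and 5.27 to 12.6 for housekeeping genes, and these 6 lists passed under all 8 alternatives. Seed storage genes had no peak under any of the 8 and never passed. These 8 are counted among the 75 and say little about stability. The excess of peaks at gene ends ranged from 1.35-fold to 2.59-fold. The circadian clock list did not pass with windows of 500 bp (odds ratio 2.70), with the higher-scoring 1467 peaks (2.56) or 733 peaks (4.84), with the nearest gene end (3.45) or with peaks that touched 1 gene (2.17). The photosystem and Rubisco list did not pass with 1467 peaks (1.90), 733 peaks (1.67) or midpoints (1.81), and turned below 1 with peaks that touched 1 gene (0.797); the core histone list did not pass there either (1.09). Fewer bound list members remain by construction in these settings, and another cause was not tested. The setting with peaks that touched 1 gene was not matched on intergenic space. The median of that space was 1159 bp for core histones and 5657 bp for the list of CDK inhibitors and D-type cyclins. Odds ratios in that setting are therefore not directly comparable between such lists. The number of bound genes was 3582, and 1987, 1091 and 1102 with 1467 peaks, 733 peaks and peaks that touched 1 gene, each of which uses fewer peaks. The low count on chromosome 2 did not pass against gene number (0.894). The motif alternatives were not run, since no genome sequence was used. No paired analysis was possible because there was 1 ChIP library with 1 peak list; for the same reason no library was left out. The read depth is unknown, so binding too weak for the authors' threshold was not detectable.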

Other observations

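The lists in this paragraph and the next were chosen after the data were seen. Genes of sister chromatid cohesion, condensin and SMC complexes were bound in 16 of 22 cases (72.7%, 95% Wilson interval 51.8 to 86.8%; odds ratio 17.8; Fisher's exact test, adjusted p = 1.18e-09 over 5 lists), led by SYN1 (a meiotic cohesin subunit, 193.2), SMC2B (a condensin subunit, 113.2) and SMC6B (76.1). DNA repair genes were bound in 13 of 21 cases (61.9%, 40.9 to 79.2%; odds ratio 10.9; Fisher's exact test, adjusted p = 5.7e-07). Among them were BARD1 (270.7), RPA1B (138.1), BRCA1 (69.7) and MSH6, whose peak of 106.2 also touched the replication gene MCM7. Genes of DNA methylation and heterochromatin maintenance were bound in 7 of 9 cases (77.8%, 45.3 to 93.7%; Fisher's exact test, adjusted p = 3.02e-05), with scores of 130.5 for MET1, the maintenance DNA methyltransferase, and 44.0 for VIM1. The highest peaks of MET1 and VIM1 touched 1 gene each, while those of SYN1, SMC2B, SMC6B, BARD1, RPA1B and BRCA1 touched 2 each. The lists of this paragraph were not tested with only the peaks that touched 1 gene. Subunits of the anaphase-promoting complex were bound in 4 of 11 cases and did not pass the correction (Fisher's exact test, adjusted p = 0.0560). Growth-regulating factors and meristem regulators were bound in 1 of 14 cases (odds ratio 0.512; Fisher's exact test, adjusted p = 1).

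A scan of 233 groups of genes that share the letters of their symbol, each with at least 8 members, gave 6 groups with more bound genes than other genes and 1 with fewer. MCM (8 of 8), CYCA (7 of 9), CYCB (7 of 9) and RAD (8 of 15) overlap with the cell cycle and repair lists. The CYCB count goes by symbol, so it includes CYCB1;5, not in the fixed list and not bound, and leaves out CYCB1;2, which the gene table calls CYC1BAT. The others were GSL, callose synthases (6 of 9; Fisher's exact test, adjusted p = 0.0113), among them GSL12 (136.9) and GSL11 (86.9), and OTP (6 of 10; Fisher's exact test, adjusted p = 0.0215), among them OTP82 (49.6). CYP, mostly cytochrome P450 genes, was bound in 8 of 229 cases (3.49%; Fisher's exact test, adjusted p = 0.000117).

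The first pattern is the high share of bound cell cycle genes; the comparison with control genes was chosen after the result was seen. Longer intergenic space was argued against by the matched lists, in which the G2/M count lay at percentile 100. Among the controls, the housekeeping count also lay at percentile 100 of its matched lists. The photosystem and Rubisco count lay at 99.3 and the circadian clock count at 99.005. These percentiles therefore do not set the cell cycle lists apart from those controls. The seed storage count lay at 9.15. Peaks of neighbouring genes were argued against as the whole cause by an odds ratio of 10.7 for the G2/M list with peaks that touched 1 gene. In that setting the housekeeping control list had 9.62, so the setting does not set the cell cycle lists apart from this control. Signal at any abundantly transcribed gene was argued against as the whole cause by the 733 highest-scoring peaks. There the odds ratio was 52.8 (33.2 to 85.7) for the 3 cell cycle lists and 3.27 (1.25 to 7.24) for housekeeping, photosystem and Rubisco genes. This holds as far as these control genes stand for abundantly transcribed genes, since transcript levels were not analysed. Housekeeping genes alone had 5.27 (1.56 to 14.2) there, so a contribution of such signal stays open. No other genotype or antibody was analysed here, and no biological explanation was tested.

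The second pattern is the peaks at housekeeping and photosystem genes. The tests by score, without tubulins, by gene set and against the housekeeping share were chosen after the result was seen. The first criterion for low-scoring peaks was an interval that included 1 in the 733 highest-scoring peaks. It was met by the housekeeping genes other than tubulins, and would be met by the photosystem and Rubisco genes, before a stricter one replaced it. The stricter one also asked that interval to end below the interval with all peaks. Sets of so few genes could not meet this even without a bound member in the 733 peaks. The stricter criterion therefore decides nothing for these genes. Binding at tubulin genes alone was argued against, since 10 of the 14 other housekeeping genes were bound (71.4%, 45.4 to 88.3%). Among these 10, EF1A2 and EF1A3 were bound through the same peak. Of 62 annotated ribosomal protein genes, 9 were bound (14.5%, 7.83 to 25.3%). The 62 were the genes whose symbol or synonyms held the words ribosomal protein, so the set may leave out others. By the criterion set beforehand against the share of all genes (13.1%), signal at any abundantly transcribed gene was left undecided. That explanation stays open for the photosystem and Rubisco list (16.1 to 46.6%). The later comparison argues against it for the housekeeping list, whose interval lay higher (45.8 to 79.3%), as far as these 62 genes stand for abundantly transcribed genes. Low-scoring peaks alone were argued against for tubulins (odds ratio 9.69, 2.22 to 33.7, in the 733 highest-scoring peaks). This rests on 4 of 14 tubulin genes (TUA2, TUB7, TUB3 and TUB8), and the highest peak of each touched 2 genes. Peaks below the median score alone were argued against for the other housekeeping genes (7.13, 1.88 to 23.7, in the 1467 at or above it). Of these genes 5 of 14 were bound there, and EF1A2 and EF1A3 shared 1 peak (19.9) that counted for both. Whether the interval stays above 1 with that peak counted once was not tested. A source outside the 733 highest-scoring peaks stays open for the other housekeeping genes (1.86, 0.0437 to 12.4). It also stays open for photosystem and Rubisco genes (1.67, 0.193 to 6.60, and 1.90, 0.483 to 5.46, in the 1467). In the 734 lowest-scoring peaks the odds ratios of these sets were 8.13 (1.45 to 30.9) and 4.42 (1.12 to 12.7). Transcript levels were not analysed here, so that ribosomal protein genes are abundantly transcribed is general knowledge and not a measurement, and no biological explanation was tested.

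The third pattern is a set of peaks at tRNA genes; its tests by score and by distance from gene ends were chosen after the count was seen, and the criterion for weak background, first set on the highest scores alone and then met, was afterwards widened to the lowest scores. Of 625 tRNA genes, 104 (16.6%) lay within 200 bp of a peak, against 22.1 on average and at most 37 in 1000 random placements at the same distances from protein-coding gene ends, which argues against closeness to gene ends as the whole cause. There were 100 separate peaks near tRNA genes, against at most 36 in the placements. These peaks were not grouped by tandem array, and several could lie in the same array. Their count therefore does not decide whether a few tandem arrays gave the pattern. Of these 100 peaks, 14 (14%, 8.53 to 22.1%) were among the 733 with the highest scores, against 25.4% of other peaks, but 21 (21%, 14.2 to 30.0%) were among the 734 with the lowest scores, against 25.2% of other peaks, and the median score was 15.8 against 17.4. Under the widened criterion these values do not decide whether background signal weaker than at other peaks gave the pattern, reads shared between near-identical tRNA copies were not assessed, and no biological explanation was tested.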
